A study of Mus musculus with 4 samples.

How the data were processed

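Cells released from the femoral epiphysis of wild-type mice were profiled by droplet single-cell RNA sequencing on postnatal days 7, 8, 10 and 12, with 1 library per day and 4 libraries in all. Per the labels' protocols, tissue was digested with enzymes at body temperature, passed through a strainer and depleted of red blood cells, and the cells were encapsulated on a MobiDrop MobiNova-100 instrument. The same protocol text names bowel tumour tissue at the digestion step, so whether these steps are the ones used on the epiphysis is open. The kit reads the 3' end of transcripts with a barcode per cell. The number of animals behind each library is not given in the sources used here.

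The deposited values were counts of unique molecular identifiers (UMIs) per gene and cell barcode, not normalized, as whole numbers in the files show. The genome build was GRCm39 per the submitters' processing notes. The counting program, its version, the gene annotation and the rule that called barcodes as cells are not given in the sources used here. The lowest UMI total of a deposited barcode was 501, 500, 1043 and 747 on days 7, 8, 10 and 12, so the rule that called cells left different minimums in the 4 libraries. Gene symbols were taken from the files, which hold 55416 features, and no coordinates are given because the reference at hand was of another build.

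Cells were kept with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs. This left 11308, 11464, 10028 and 16253 cells on days 7, 8, 10 and 12 out of 12886, 12469, 10729 and 18108 barcodes. Scrublet, run within each library in its Scanpy form at an expected rate of 0.06 with 30 components, marked only 2 barcodes (0.00369%), so the caller did not work on these libraries. The marked cells were left out, and an alternative took out the 6% of cells with the highest scores in each library.

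Counts per cell were scaled to 10000 and log-transformed, 2000 variable genes were chosen within libraries, and 40 principal components, 20 neighbours and Leiden clustering at resolution 1 gave 40 clusters without batch integration. Hemoglobin, mitochondrial, ribosomal and sex-linked genes were left out of the variable genes. The design, the cell filter, the markers of 22 cell classes and 30 gene lists were fixed before the data were examined.

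A cluster took the name of the class with the largest share of its markers at least 2-fold above the other clusters and detected in at least 10% of cells, with at least 3 markers and 50% of the list. This scoring rule, and its refusal of clusters whose markers pointed to competing classes, was set after looking at the clusters. It left 8 clusters unnamed, holding 17.9%, 21.0%, 25.8% and 21.0% of cells on days 7, 8, 10 and 12. The largest of these were clusters 2 (13.5%, 14.7%, 0.0199% and 0.154% of cells), 3 (0.159%, 0.113%, 6.83% and 13.9%), 6 (0, 0.00872%, 17.2% and 0.375%) and 15 (2.93%, 5.67%, 1.02% and 0.708%). Clusters 25 (0.0442%, 0.314%, 0.339% and 4.60%), 36 (0, 0, 0.199% and 1.06%), 37 (1.21%, 0.183%, 0.0499% and 0.0246%) and 39 (0, 0, 0.0798% and 0.142%) were smaller. A count of 0 allows a share of up to 0.0265% on day 7 and 0.0262% on day 8. A hematopoietic stem and progenitor cluster did not separate, so the cells of the progenitor clusters were clustered again at resolution 1 and the subset with those markers was taken, a step added after seeing the data.

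Raw counts were summed per library and class for the 4 classes with at least 50 cells in every library: chondrocyte, endothelial, fibroblast and reticular stromal. Sums were expressed as CPM, the usual scaling of a gene's counts to the class total of its library. Ratios of day 12 to day 7 were computed with 1 UMI added to each sum. Each day is 1 library, so no test between days was possible and no p-values are given. CPM carry exact Poisson intervals and shares of cells exact Clopper-Pearson intervals, both at 95%, and these cover counting error only. An undetected gene or class is given with the limit that 3 counts would set.

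For each list, the median log2 ratio over genes with at least 20 UMIs in the class was set beside 10000 random lists of the same size matched on mean expression in 20 bins. Interval bounds on list medians came from 1000 Poisson redraws of the counts. Members were counted as higher or lower from 1.5-fold. The percentile among random lists describes these libraries and is not a test. The lists cover cartilage matrix, resting, prehypertrophic, hypertrophic and articular cartilage, cell division, hypoxia, angiogenic ligands and inhibitors, matrix proteases, imprinted and growth-decline genes, endothelial types, hemogenic and stem cell genes, mesenchymal transition, niche factors, interferon, dissociation stress, inflammation, hemoglobin, neutrophil granules, sex-linked genes and 5 lineage gates.

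Genes named outside the lists followed a rule of size. In each of the 4 classes it took the 10 genes with the largest and the 10 with the smallest ratio of day 12 to day 7. They needed at least 50 CPM on at least 1 day, at least 100 UMIs over the 4 libraries, intervals on days 7 and 12 that did not overlap and levels that went one way over the 4 days. Hemoglobin, mitochondrial, ribosomal, sex-linked, immunoglobulin and numbered genes were left out. So were genes more than 5-fold higher in another class, among classes with enough UMIs in every library. Neutrophil-like and B-lineage-like cells, with 5 and 9 cells on day 7, fell short of that. Free RNA of such classes was therefore not screened out of the named genes.

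Shares of cells with a UMI were computed after thinning each cell to 1000 UMIs, which left out no cell of the classes compared. A cell was positive for a lineage gate with UMIs of at least 3 of its genes. The share of cells positive for both gates of a pair was divided by 2 times the product of their shares, so that 0.5 is the value for independent gates.

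The ratio step was tested on simulated counts drawn from the real class totals, with 200 genes changed by 4-fold. For day 12 over day 7 in chondrocytes, over 14052 genes, 100% of genes set higher and 99% of genes set lower had intervals that separated in that direction. In endothelial cells, over 10264 genes, the shares were 93% and 73%. Intervals of unchanged genes separated for 0.686% in chondrocytes and 1.39% in endothelial cells. Apart from the changed genes, the simulated days shared the same profile and differed by counting error only. These shares therefore do not estimate how often real libraries differ for reasons other than day.

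Alternatives changed the cell filter, doublet removal, clustering resolution and components, the denominator and class assignment, the scaling of sums (TMM factors from edgeR, or totals without blood and mitochondrial genes), the depth per cell, the count minimum and the number of genes per gate. TMM factors move every log2 ratio of day 12 to day 7 by -0.16 in chondrocytes, -0.21 in endothelial cells, -0.17 in fibroblasts and -0.31 in reticular stromal cells. Work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, Scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, with the random seed at 0.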

Results

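The femoral epiphysis, the end of the growing thigh bone, consists of cartilage at birth and is later invaded by vessels, bone and marrow. Its cells were profiled by single-cell RNA sequencing in wild-type mice on postnatal days 7, 8, 10 and 12, with 1 library per day and no replicates. As the series title states, the study concerned whether cartilage cells can give rise to hematopoietic stem cells by way of endothelial cells. The libraries held 44218720, 46534365, 132282322 and 169323978 UMIs on days 7, 8, 10 and 12. The cells kept had a median of 3103, 3168.5, 7706.5 and 6563 UMIs and of 1336, 1399.5, 2149.5 and 2574 genes, so depth per cell was higher in the day-10 and day-12 libraries.

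The first comparison asked which cell types the epiphysis held as cartilage gave way to marrow. Chondrocyte-like cells, the cells that make cartilage, formed 73.7% of the day-7 library (8330 of 11308 cells, interval 72.8 to 74.5), 48.2% of the day-8 library (47.2 to 49.1), 1.53% of the day-10 library (1.29 to 1.79) and 8.94% of the day-12 library (8.51 to 9.39). All hematopoietic classes together went the other way, with 2.11%, 7.15%, 50.1% and 47.8% of cells on days 7, 8, 10 and 12. Endothelial-like cells, which line vessels, made up 0.531% on day 7 (60 cells, interval 0.405 to 0.682), 2.85% on day 8, 4.22% on day 10 and 3.49% on day 12 (567 cells, interval 3.21 to 3.78).

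Blood lineages differed in when they were most frequent. Erythroid-like cells held 0.345%, 0.515%, 24.9% and 7.19% of cells on days 7, 8, 10 and 12, after a red-cell removal step of unknown efficiency, described in a protocol text that names another tissue. Neutrophil-like cells held 0.0442%, 0.105%, 5.40% and 7.75%, and B-lineage-like cells 0.0796%, 0.297%, 8.68% and 7.02%. Monocyte- or macrophage-like cells were already at 1.12% and 4.38% on days 7 and 8, ahead of 5.48% and 11.0% on days 10 and 12. A subset with stem and progenitor markers, led by Flt3, a receptor of early multipotent progenitors, and holding Hlf, a transcription factor of stem cells, was found only on days 10 and 12. It comprised 35 of 5020 hematopoietic cells on day 10 (0.697%, interval 0.486 to 0.968) and 66 of 7773 on day 12 (0.849%, interval 0.657 to 1.08). None of 239 hematopoietic cells on day 7 and none of 820 on day 8 belonged to it, which allows shares of up to 1.26% and 0.366%. By cell number alone, a subset of the day-12 frequency could have been missed on day 7 but not on day 8. These limits assume that such cells would join the same subset on every day, which was not tested. Libraries were not integrated, and a progenitor subset led by Hspa1a held 12 cells of day 7, 15 of day 8 and none of days 10 and 12.

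Bone-forming and bone-resorbing cells were most frequent in the day-12 library. Osteoblast-lineage-like cells stood at 0.265%, 0.445%, 0.618% and 5.41% on days 7, 8, 10 and 12, and osteoclast-like cells, which resorb cartilage and bone, at 0.345%, 0.977%, 1.46% and 8.05%. Tendon- or ligament-like cells were at 3.21%, 12.5%, 8.42% and 4.61%, and fibroblast-like cells at 1.14%, 4.8%, 4.14% and 3.17%.

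The chondrocyte share on day 10 lay below that on day 12, outside both intervals, so the 4 values did not follow the order of age. With unnamed clusters of cartilage markers counted, the shares were 91.5%, 69.1%, 9.78% and 28.4%, and the log2 ratio of day 12 to day 7 was -1.69 in place of -3.04. Not all of these cells are settled as cartilage. On day 12 they included 2265 cells of cluster 3, which held 88.2% of chondrocyte and 85.7% of tendon or ligament markers. Another 747 were of cluster 25, which held markers of blood and non-blood classes together. For endothelial cells the ratio of 2.72 rested on day 7 as the baseline and was 0.29 with day 8 in its place.

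**Figure D1:**
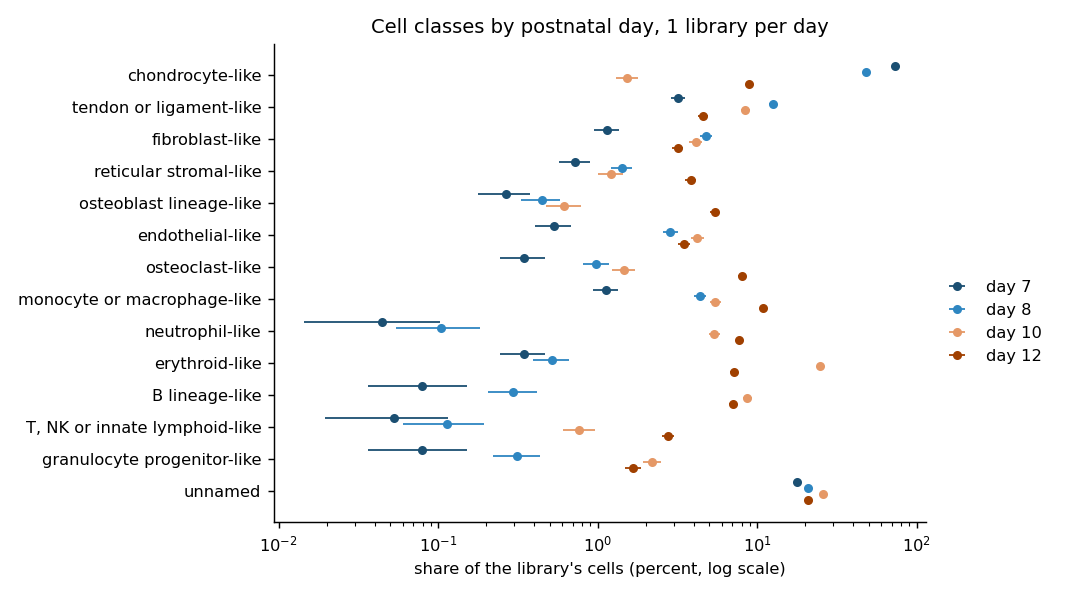
Share of each library's cells in each cell class (percent, log scale) on postnatal days 7, 8, 10 and 12, 1 library per day, with points for shares and bars for exact 95% intervals that cover counting error only. Chondrocyte-like cells lay at 73.7% on day 7 and 8.94% on day 12, and erythroid-like cells at 0.345% and 24.9% on days 7 and 10.

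The next comparison asked how chondrocytes themselves differed between days. In the day-12 library, chondrocyte-like cells carried more transcripts of maturing growth cartilage, and fewer of its reserve zone as long as unnamed cartilage clusters were not counted. Col10a1 (ENSMUSG00000039462.5), the collagen of hypertrophic chondrocytes, was 19.5-fold higher on day 12 than on day 7, at 4141 CPM (interval 4116 to 4167) against 212 CPM (207 to 218). Ucma (ENSMUSG00000026668.11), a secreted protein of resting and upper-zone cartilage, was 4.27-fold lower, at 897 CPM on day 12 against 3825 CPM on day 7.

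Of 8 measured hypertrophic genes, 6 were at least 1.5-fold higher and 1 lower on day 12, with a median log2 ratio of 2.36 (interval 2.29 to 2.41), above all 10000 random lists of matched expression, whose median was 0.28. Panx3, a channel protein of hypertrophic cells, stood at 1043 against 194 CPM, and Sp7, a transcription factor of bone formation, at 186 against 20.8 CPM. The gene that went the other way was Vegfa, the main vessel growth factor, at 16.5 CPM on day 12 and 38.7 CPM on day 7. All 6 prehypertrophic genes were higher, with a median of 1.74, among them Ihh, the hedgehog ligand of the growth plate, at 151 against 43.1 CPM. Pth1r, the receptor for parathyroid hormone-related protein, was at 444 against 135 CPM. The hypertrophic list also had a median of 1.80 in endothelial-like cells, with their subsets led by blood or cartilage genes left out. Transcripts of this list were thus also higher outside chondrocyte-like cells. Hemoglobin genes still had a median of 4.25 in the same endothelial-like cells, so RNA of other cells remained there. The 1.80 is therefore not read as expression by endothelial cells.

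Among the 8 resting-zone genes, 7 were lower and 1 higher on day 12, with a median log2 ratio of -2.25, below all random lists, which was -0.71 within clusters and 0.26 with unnamed cartilage clusters counted. Pthlh, the ligand that holds chondrocytes immature, stood at 2.70 against 14.5 CPM, and Grem1, a BMP antagonist, at 3.36 against 29.6 CPM. Sfrp5, a Wnt antagonist, was the exception at 130 against 84.0 CPM. Cartilage matrix genes had a median of 0.53, at percentile 92.7 of random lists, with 7 of 15 higher and 1 lower; Acan, the main proteoglycan, was at 6522 against 2439 CPM and Col2a1, the main cartilage collagen, at 60529 against 47905 CPM. Articular-surface genes had a median of -0.94 with 4 of 7 lower, and Prg4, the lubricin of joint surfaces, was at 105 against 753 CPM.

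Cell division genes were higher in day-12 chondrocytes, 15 of 18 by at least 1.5-fold and none lower, with a median of 1.10. Unnamed cluster 15, led by Prc1, Spc25 and Cenpf and holding 94.1% of chondrocyte markers, was not part of this class. It held 331, 650, 102 and 115 cells on days 7, 8, 10 and 12. Imprinted and growth-decline genes had a median of -0.67, with 9 of 16 lower and 1 higher. Dlk1, an imprinted Notch-like protein of immature cells, was 30.6-fold lower, at 70.5 CPM on day 12 and 2155 CPM on day 7, and the imprinted transcript Meg3 was at 343 against 2703 CPM. Lin28b, an RNA-binding protein of fetal and early postnatal tissue, was at 1.72 against 50.0 CPM.

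Other genes with the largest ratios that went one way over the 4 days included Serinc5 (766 against 113 CPM), the BMP antagonist Chrdl1 (129 against 16.9 CPM) and Dlx5, a homeobox factor of skeletal maturation (77.6 against 13.2 CPM). The citrate transporter Slc13a5, the collagen-modifying enzyme P3h2, the fatty acid desaturase Scd1, Slc35g1, Grb14 and Magel2 were also on this list, between 5.08-fold and 6.65-fold higher. Lowest against day 7 were the metallothionein genes Mt2, 56.3-fold lower at 14.8 against 836 CPM, and Mt1, 17.7-fold lower. H2bc6, Sorbs2os, Selenbp1, Lbhd2 and Lrrc4 were between 14.7-fold and 24.1-fold lower. Of the 10 lower genes that the rule of size took, 7 were at least 2-fold lower in endothelial, fibroblast and reticular stromal cells as well, against 2 of the 10 higher genes.

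Stress and blood transcripts moved with these groups. Dissociation stress genes, which enzymatic digestion induces, had a median of -1.70 with 13 of 14 lower, and Hspa1a, an inducible heat-shock protein, was at 15.9 CPM on day 12 and 265 CPM on day 7. Hemoglobin genes had a median of 2.39, neutrophil granule genes of 3.99 and genes of the pan-hematopoietic gate of 2.47 in the same chondrocyte-like cells. With day 8 as the baseline the hemoglobin median reversed to -0.18, and Hbb-bs, an adult beta-globin gene, stood at 349, 2178, 5152 and 1902 CPM on days 7, 8, 10 and 12.

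Vessel-related lists moved less in chondrocytes: angiogenic ligands had a median of -0.33 (3 of 12 higher, 5 lower), angiogenesis inhibitors of -0.47 (2 of 8 higher, 3 lower), hypoxia and glycolysis genes of 0.23 and matrix proteases of 0.03. Mesenchymal transition genes had a median of 0.23 and niche factors, which sustain blood progenitors, of 0.05, both near the middle of random lists.

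Cluster 0 held 46.6% of chondrocyte-like cells on day 7 and 0.138% on day 12, whereas cluster 18, led by Col10a1, held 0.144% and 66.4%, so cells of different clusters were compared. Within the 3 clusters with at least 100 cells on both days (1, 16 and 27), the median was 1.90 for hypertrophic, -0.71 for resting-zone and 0.49 for articular-surface genes, and with unnamed cartilage clusters counted it was 1.92, 0.26 and 0.80, so the articular-surface list reversed in both settings and the resting-zone list in the latter.

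**Figure D2:**
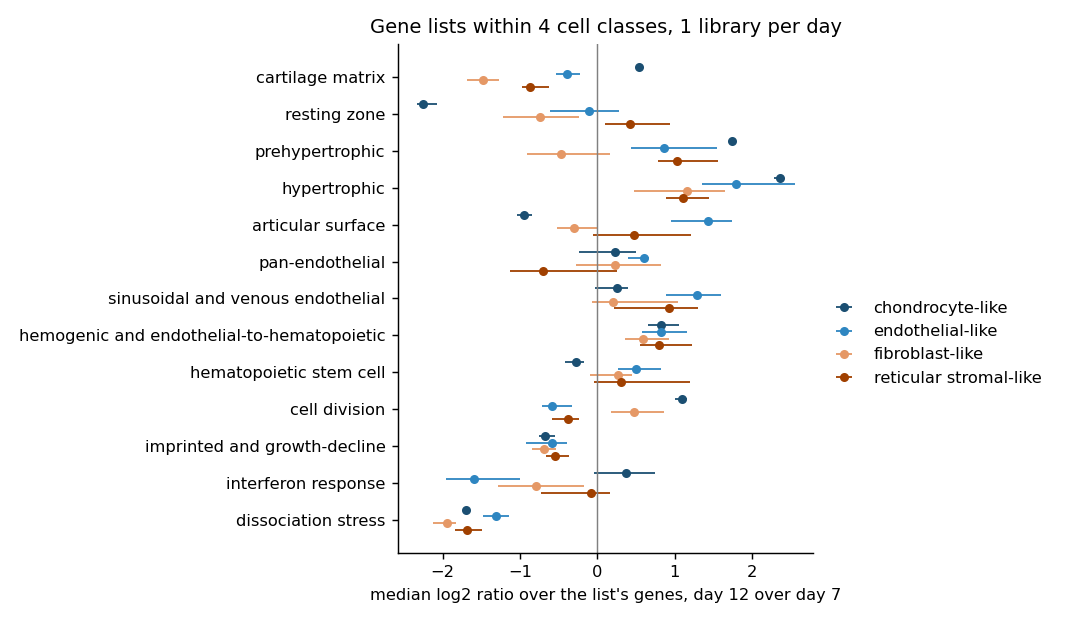
Median log2 ratio of day 12 to day 7 over the genes of each list in 4 cell classes, 1 library per day, with points for medians and bars for intervals from Poisson redraws, which cover counting error only. In chondrocyte-like cells hypertrophic genes lay at 2.36 and resting-zone genes at -2.25, and dissociation stress genes lay at -1.31 or below in all 4 classes.

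The third comparison concerned endothelial cells, the proposed intermediate. Endothelial-like cells of the day-12 library carried more transcripts of marrow sinusoids, the wide vessels through which blood cells leave the marrow, than those of day 7. Stab2 (ENSMUSG00000035459.19), a scavenger receptor of sinusoidal endothelium, had no UMI in 387426 endothelial UMIs on day 7, which allows up to 7.74 CPM, and stood at 96.1 CPM on day 12 (interval 88.8 to 104), at least 12.4-fold higher. Stab1, its relative, was at 204 against 33.6 CPM, the venous transcription factor Nr2f2 at 317 against 95.5 CPM and the venous receptor Ephb4 at 158 against 43.9 CPM.

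The sinusoidal and venous list had a median log2 ratio of 1.29 (interval 0.88 to 1.59), above all random lists, with 7 of 12 members at least 1.5-fold higher. Its 1 lower member was Selp, an adhesion molecule of activated endothelium, at 69.1 against 454 CPM. Pan-endothelial genes had a median of 0.60 with 9 of 17 higher and 2 lower, among them Cdh5, the junction cadherin of endothelium, at 1809 against 857 CPM. Arterial genes had a median of 0.52 (percentile 91.9) and tip-cell genes of 0.32 (percentile 74.7), near random lists.

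Hemogenic genes, which act when endothelium gives rise to blood cells, had a median of 0.82 in endothelial cells with 10 of 18 higher and 1 lower. The same list had medians of 0.82 in chondrocytes, 0.59 in fibroblasts and 0.79 in reticular stromal cells. Runx1 (ENSMUSG00000022952.18), the transcription factor required for that step, was at 66.7 CPM on day 12 (interval 60.6 to 73.2) and 25.8 CPM on day 7 (12.4 to 47.5), and Gata2 at 62.3 CPM (56.4 to 68.6) and 38.7 CPM (21.7 to 63.9), which overlap. Hematopoietic stem cell genes had a median of 0.50, with 7 of 16 higher and 1 lower. In endothelial cells the pan-hematopoietic gate genes had a median of 4.25, hemoglobin genes of 4.25 and neutrophil granule genes of 4.14.

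Several inflammatory genes and most interferon genes were lower in day-12 endothelium. Inflammation genes had a median of -1.24 (interval -1.63 to 0.27) with 6 of 11 lower and 5 higher, which was -2.10 without the subsets led by blood or cartilage genes, and Il6, a cytokine, was at 8.62 against 336 CPM. Cxcl1, a chemokine that recruits neutrophils, was at 5.44 against 232 CPM and Icam1, an adhesion molecule for leukocytes, at 77.2 against 645 CPM. Interferon-response genes had a median of -1.59, though with day 8 as the baseline the median was 0.16. Dissociation stress genes had a median of -1.31 with 12 of 14 lower, and Hspa1a was at 10.9 against 617 CPM. Cell division genes were lower as well, with a median of -0.58 and 9 of 18 lower against 3 higher.

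The other endothelial genes with the largest ratios were Egfem1 (135 CPM on day 12, and 2.58 CPM on day 7 with an interval of 0.0653 to 14.4 from 1 UMI), Npnt, an integrin ligand (212 against 23.2 CPM), Fam102a (113 against 10.3 CPM), Gramd4, Pld5 and Rpa1. The class II antigen presentation genes H2-Aa, H2-Ab1 and H2-Eb1, carried by B and dendritic cells, stood at 81.5, 67.4 and 70.9 CPM on day 12, against 1 UMI each (2.58 CPM, interval 0.0653 to 14.4) on day 7. Genes with the largest ratios downward also included Gadd45g and Angpt2, a destabilizer of vessels, at 28.0 against 235 CPM and 18.0 against 95.5 CPM, with Mrpl23, Atp5g2, H4c4, Rbm3, Casp4 and Map3k8. Of these 10 lower genes, 7 were at least 2-fold lower in the 3 other classes.

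Only 60 endothelial-like cells stood behind day 7. In a second clustering of the class, 78.3% of its cells on day 7 and 88.1% on day 8 fell in a subset led by Hspa1a, Il6 and Cxcl1 that held none of 567 cells on day 12 (up to 0.529%), and 3 subsets were led by blood or cartilage genes; without those 3 the medians were 1.5 for sinusoidal and venous and 0.71 for hemogenic genes, and that of neutrophil granule genes was 1.86, while that of hemoglobin genes was still 4.25.

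The fourth comparison asked in which endothelial cells hemogenic genes were found. After thinning each cell to 1000 UMIs, 7 of 19 hemogenic genes were detected in a larger share of endothelial-like cells than of chondrocyte-like and fibroblast-like cells on day 12, beyond the intervals. These were Adgrg1, Gata2, Kit, Lmo2, Lyl1, Ptprc and Tal1. Adgrg1, a receptor of stem cells and endothelium, was found in 11.5% of endothelial-like cells (interval 8.96 to 14.4), 0.138% of chondrocyte-like cells and none of 516 fibroblast-like cells, which allows up to 0.581%. Lmo2 was found in 9.17%, 0.688% and 0.388% of these classes, Gata2 in 7.76%, 0.0688% and 0.388%, Kit in 7.23%, 0.0688% and 0.388% and Tal1 in 5.82%, 0.138% and 0.581%. Lmo2, Gata2 and Tal1 are transcription regulators shared by endothelium and blood. With the subsets led by blood or cartilage genes left out of the endothelial class alone, 375 endothelial-like cells remained on day 12 and 5 of the 19 genes stood apart, Adgrg1 (12.3%), Lmo2 (9.07%), Gata2 (8.53%), Kit (8.27%) and Tal1 (5.33%). Ptprc, at 4% (interval 2.26 to 6.51), and Lyl1, at 1.6% (0.589 to 3.45), did not. Blood-led cells stayed in the chondrocyte-like class, so this loss of separation is not read as a result.

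Runx1 was not found in a larger share of endothelial-like cells than of chondrocyte-like and fibroblast-like cells on any of the 4 days. It was found in 5.64% of endothelial-like cells on day 12 (32 of 567, interval 3.89 to 7.87), 6.26% of chondrocyte-like cells (5.07 to 7.63) and 6.59% of fibroblast-like cells (4.61 to 9.09), against 19.4% of neutrophil-like cells (17.3 to 21.7). Without the mixed subsets its endothelial share was 2.67% (1.29 to 4.85), though a blood-led subset of chondrocyte-like cells, 9.22% of the class on day 12, was not left out, so these shares are not compared. On day 8 the share was lower in endothelial-like cells, at 3.36% (1.69 to 5.94), than in chondrocyte-like cells, at 11.6% (10.7 to 12.4), and in fibroblast-like cells, at 8.18% (6.03 to 10.8). On day 7 it was 1.67% (0.0422 to 8.94) against 11.9% (11.2 to 12.6) of chondrocyte-like cells. Chondrocyte-like cells thus carried Runx1 on day 7 with little Ptprc, a blood gene found in 0.228% of them. They are not a background level for Runx1, so a share no larger than theirs does not show that endothelial-like cells lacked it. Without thinning the day-12 shares of Runx1 were 29.5%, 43.6%, 33.1% and 36.7%, at median depths of 8218, 14613, 7906 and 1803.5 UMIs. Gfi1 and Gfi1b repress endothelial genes during the transition to blood. After thinning they were found in 0 of 567 endothelial-like cells, which allows up to 0.529%. Their shares of neutrophil-like cells were only 0.0794% and 0.238%, so the 0 of Gfi1 decides nothing at this depth. Gfi1b was, without thinning, among the leading genes of a progenitor subset of 147 cells with a median of 1782 UMIs. It was thus detectable in shallow cells, and neutrophil-like cells do not set its limit. Ptprc, which encodes the leukocyte antigen CD45, was in 7.58% of endothelial-like, 2.48% of chondrocyte-like and 3.49% of fibroblast-like cells, against 68.3% of neutrophil-like cells.

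On day 7 none of the 19 genes separated endothelial cells in this way, on day 8 there were 6 (Adgrg1, Gata2, Kit, Lmo2, Mecom and Tal1) and on day 10 there were 4 (Adgrg1, Lmo2, Mecom and Tal1). The 60 endothelial cells of day 7 set a limit of 5% for a gene with no UMI there.

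**Figure D3:**
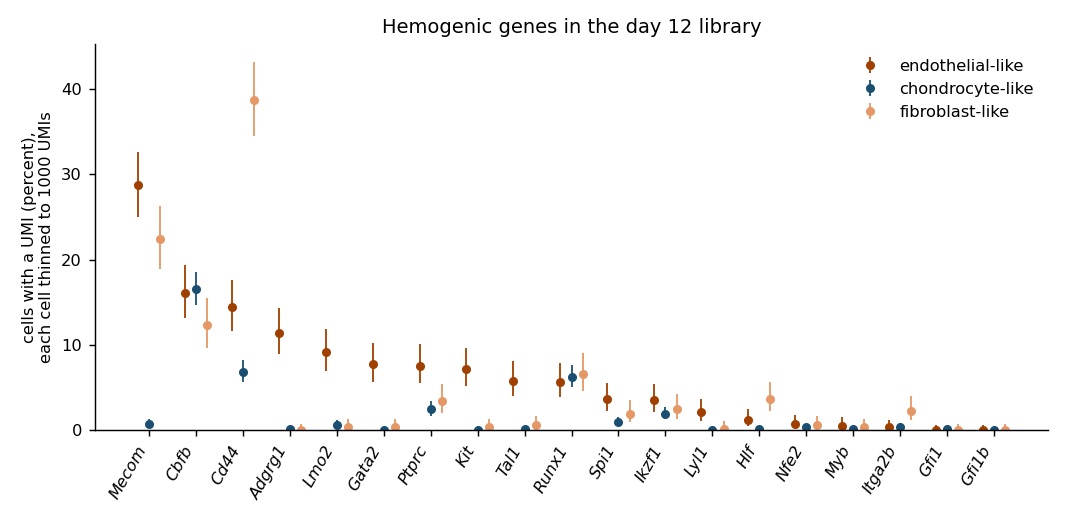
Share of cells (percent) with at least 1 UMI of each hemogenic gene in endothelial-like, chondrocyte-like and fibroblast-like cells of the day-12 library, each cell thinned to 1000 UMIs, with points for shares and bars for exact 95% intervals. Adgrg1 lay at 11.5% in endothelial-like cells and 0.138% in chondrocyte-like cells, and Runx1 at 5.64% and 6.26%.

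The last comparison counted cells that carried genes of 2 lineages, as cells in passage from cartilage to endothelium or from endothelium to blood would. Cells positive for the chondrocyte and endothelial gates together had a ratio of 0.492, 0.489, 0.512 and 0.499 on days 7, 8, 10 and 12, where independence gives 0.5. Gates of separate cell types without mixed transcripts would lie below 0.5. A ratio of 0.5 therefore does not show that mixed cells were lacking. Chondrocyte and pan-hematopoietic genes, a pair with no proposed transition, gave 0.498, 0.496, 0.487 and 0.488, and chondrocyte and erythroid genes 0.50, 0.493, 0.482 and 0.490. Cells positive for the endothelial and pan-hematopoietic gates gave 0 (interval up to 1.73, so day 7 decides nothing), 0.118, 0.517 and 0.35, and fibroblast and pan-hematopoietic genes 0.228, 0.257, 0.478 and 0.393.

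On day 12, 749 cells carried chondrocyte and endothelial genes (4.61%, interval 4.29 to 4.94) and 269 carried endothelial and pan-hematopoietic genes (1.65%, interval 1.46 to 1.86). Cells of this last kind had a median of 10281 UMIs, against 6734 in cells positive for the endothelial gate alone and 5213 in those positive for the pan-hematopoietic gate alone. On day 7 none of 11309 cells, the marked doublets included, were positive for both, which allows up to 0.0265%.

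The chondrocyte gate was met by 99.9%, 99.4%, 66.9% and 92.3% of all cells on days 7, 8, 10 and 12, which leaves its ratios little room to depart from 0.5 on days 7, 8 and 12 and more on day 10. Col2a1 was also found in cells that should lack it, at 4740, 4015, 442 and 3842 CPM in monocyte- or macrophage-like cells.

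After thinning to 1000 UMIs the chondrocyte gate was met by 19.7% of cells on day 10 and 50.7% on day 12. On day 10 the chondrocyte and endothelial ratio was then 0.336 (interval 0.256 to 0.434), against 0.236 (0.197 to 0.279) for chondrocyte and pan-hematopoietic genes, which overlaps, and 0.145 (0.116 to 0.179) for chondrocyte and erythroid genes. On day 12 it was 0.294 (0.251 to 0.341), below the 0.373 (0.356 to 0.390) of the pan-hematopoietic pair and beside the 0.333 (0.295 to 0.374) of the erythroid pair. After thinning the proposed pair thus lay above a control on day 10 and not on day 12. With at least 5 genes per gate and no thinning, its day-10 ratio was 0.356 (0.291 to 0.430). The pan-hematopoietic pair then gave 0.339 (0.310 to 0.371) and the erythroid pair 0.332 (0.297 to 0.370), which overlap with it.

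**Figure D4:**
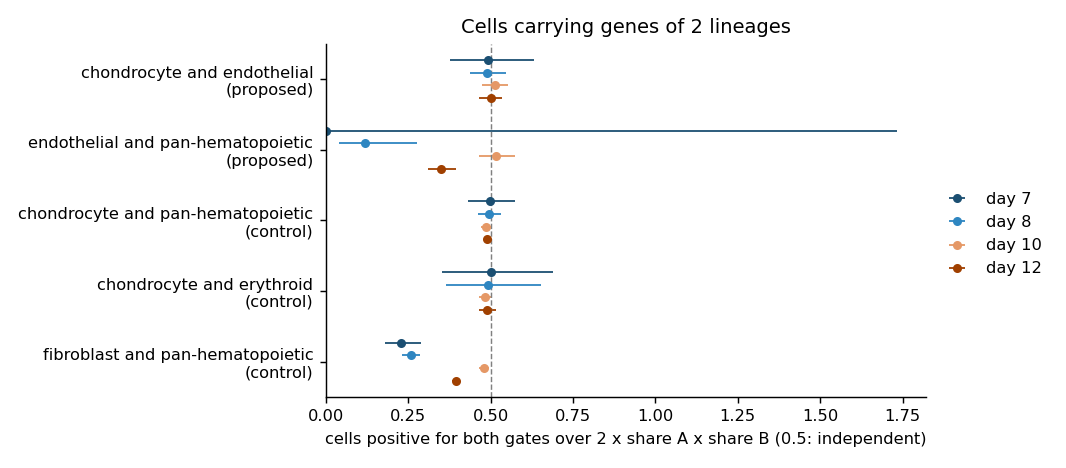
Share of cells positive for both gates of a pair over 2 times the product of the shares of each, on postnatal days 7, 8, 10 and 12, with points for ratios and bars for intervals that cover counting error only, and 0.5 as the value of independent gates. The chondrocyte and endothelial pair lay between 0.489 and 0.512, and the endothelial and pan-hematopoietic pair between 0.118 and 0.517 on days 8 to 12, while its interval on day 7 reached 1.73.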

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

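The tests of the stress genes by step between days and of the share of cells with a high cartilage load across gates were set before their results were seen. The other tests in this part were chosen after the results were seen, and the bound for free RNA was rewritten after its value was known.

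Y-linked genes and Xist, counted over all cells of each library, lay outside the comparisons of cell classes and gave a signal above the limit that a count of 0 allows. Y-linked genes together stood at 178, 92.3, 0.262 and 162 CPM on days 7, 8, 10 and 12, and Xist, the transcript of the inactive X chromosome in female cells, at 347, 653, 435 and 262 CPM. Only 34 Y-linked UMIs were counted in the day-10 library. The makeup by sex thus differed between libraries and cannot be told apart from day. Numbered gene models, also outside the comparisons, gave 1.12%, 1.19%, 0.474% and 0.387% of chondrocyte UMIs on these days. They gave 0.830%, 0.97%, 0.537% and 0.434% of endothelial UMIs.

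The chondrocyte share was higher in the day-7 and day-8 libraries than in those of days 10 and 12. Lower depth is argued against, since with cells thinned before clustering the log2 ratio of day 12 to day 7 was -2.97. Barcodes with few UMIs and no cell are argued against as well, at -2.95 under the strict filter. A difference in the tissue taken or released in each library cannot be told apart from age, because each day is 1 library, and the 1.53% of day 10 lay below day 12. Age itself, with replacement of cartilage by marrow, stays open and was not tested.

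Dissociation stress genes were lower in the day-10 and day-12 libraries. Other cell types entering a class are argued against, since the median nearest to 0 among the 4 classes was -1.31. The median in chondrocytes was -1.63 after thinning. This does not decide on lower depth, because CPM were already scaled to the class total and thinning mainly reweights cells. Handling shared by the day-7 and day-8 libraries may contribute, as the step between days 8 and 10 was the largest of the 3 steps in 3 of 4 classes. The exception was reticular stromal cells, with steps of 0.14, -0.79 and -1.33, and in endothelial cells the last steps were close, at -0.87 and -0.85. An effect of age stays open and was not tested.

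In the day-12 library, 15 of 611 cells positive for at least 5 endothelial gate genes also carried a cartilage load of at least 50% of the chondrocyte median. Their share of 2.45% (interval 1.38 to 4.02) argues against free RNA as the whole source, as these cells held 2.93 times the UMIs of the other endothelial-gate cells. A pair of cells in 1 droplet may account for them, since the share was 0.791 times that among cells positive for the pan-hematopoietic gate, where 186 of 5995 cells (3.10%) carried such a load. On day 8 the order was the other way, with 11 of 261 endothelial-gate cells (4.21%, interval 2.12 to 7.42) against 11 of 594 pan-hematopoietic-gate cells (1.85%, 0.928 to 3.29), more than 2 times as large a share with intervals that overlap. By clustering, more endothelial-like cells carried cartilage genes than by this load. A subset of the class led by Col10a1, Col11a1 and Ibsp held 5, 12, 26 and 62 cells on days 7, 8, 10 and 12. These were 8.33%, 3.67%, 6.15% and 10.9% of the class, with a median of 13961 UMIs over all days. The source of their cartilage genes was not tested. Cells in passage from cartilage to endothelium were not excluded, and no test here separates them from droplets with a pair of cells.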

How the results depend on the processing

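The settings with day 8 as baseline, cells thinned before clustering, unnamed cartilage clusters counted, the highest doublet scores removed, values within clusters and mixed endothelial subsets left out were chosen after seeing the data. No paired analysis was possible because each day is 1 library.

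The log2 ratio of the chondrocyte share, -3.04, was negative under all 10 settings that moved it. It was -2.53 with the loose and -2.95 with the strict filter, -3.23 and -2.46 at resolutions 0.5 and 2, -2.60 with 20 components and -2.97 with cells thinned before clustering. It was -2.13 over non-hematopoietic cells, which a smaller denominator explains, -0.92 by gate lists, -1.69 with unnamed cartilage clusters counted and -2.43 from day 8. The endothelial ratio, 2.72, was 3.62 over non-hematopoietic cells, 3.90 by gate lists and 0.29 from day 8. The hematopoietic ratio, 4.50, was 3.89 with the loose filter, 4.31 with the strict filter and 2.74 from day 8. Apart from the denominator, the cause was not tested.

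With day 8 as baseline, medians in chondrocytes were 0.77 for cartilage matrix, -1.99 for resting-zone and 1.77 for hypertrophic genes. Those in endothelial cells were 0.82 for sinusoidal and 1.35 for hemogenic genes. The fibroblast share (-0.60), the tendon or ligament share (-1.44), hemoglobin genes in chondrocytes (-0.18) and interferon genes in endothelial cells (0.16) reversed. The cause was not tested.

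TMM factors gave 0.37, -2.41 and 2.20 for cartilage matrix, resting-zone and hypertrophic genes in chondrocytes, by the shift of the factors. Counting unnamed cartilage clusters gave 0.20, 0.26 (reversed) and 1.92, and articular-surface genes reversed to 0.80. Within clusters the values were 0.40, -0.71 and 1.90, and articular-surface genes reversed to 0.49. Both settings compare other cells by construction. The first adds, on day 12, 2265 cells of cluster 3, which also held 85.7% of tendon or ligament markers. Marked doublets kept, which repeats the clustering, gave 0.56 for cartilage matrix and -1.99 for resting-zone genes. The strict filter gave 0.57 for cartilage matrix, and removal of the highest doublet scores 0.57 and 2.42 for cartilage matrix and hypertrophic genes. Thinning before summing gave -1.97 for resting-zone and 2.68 for hypertrophic genes. Sinusoidal genes in reticular stromal cells reversed to -0.10 without a count minimum. The cause of these was not tested.

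The share of endothelial cells with Runx1 on day 12, 5.64%, was 29.5% without thinning and 9.90% at 2000 UMIs, as more UMIs per cell detect more, and 2.67% with the mixed subsets left out, which holds fewer cells with blood genes by construction. The chondrocyte and endothelial gate ratio, 0.499, was 0.461 with at least 5 genes and 0.294 after thinning. The endothelial and pan-hematopoietic ratio, 0.35, was 0.514 with at least 2 genes, 0.224 with at least 5 and 0.116 after thinning. The cause was not tested.

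Of the other values under alternatives to the main answers, 50 stayed within their intervals. Among all other results, 1159 values stayed within them, 407 moved and 7 were counted as reversed. The 407 include gate ratios and shares of cells with a gene, which have no direction. The count of 407 therefore does not show that direction was kept. Reticular stromal cells formed no class under the strict filter or with the highest doublet scores removed, so they have no value there. The 60 endothelial cells of day 7 limit the precision of values in that class.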

Other observations

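Reticular-stromal-like cells were named after cells that surround marrow vessels and feed blood progenitors. Their cluster was led by Mmp13, Cxcl12, Mmp9 and Mmp10. It held 75% of the reticular stromal and 63.6% of the osteoblast-lineage markers, so this identity is not settled. Niche factors differed between days in both directions in these cells, with 6 of 10 genes at least 1.5-fold higher and 4 at least 1.5-fold lower on day 12. The list of niche factors in reticular stromal cells had a median log2 ratio of 0.95 (interval 0.73 to 1.11, percentile 99.7 of random lists), which was 0.64 with TMM factors and 0.17 without a count minimum. Cxcl12, the chemokine that retains stem cells in marrow, stood at 1502 CPM on day 12 and 625 CPM on day 7, Kitl, the ligand of the stem cell receptor Kit, at 279 and 131 CPM, and Vcam1, an adhesion molecule of marrow stroma, at 196 and 68.0 CPM. Igf1, a growth factor, was 5.67-fold higher. Jag1, a Notch ligand, and Il7, a lymphoid cytokine, were lower, at 51.9 against 94.9 CPM and 10.7 against 21.5 CPM.

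Among the genes with the largest ratios in reticular stromal cells, the ephrin receptor Epha3 was 9.10-fold and the iron exporter Slc40a1 6.90-fold higher, with Idh1, Vldlr, Septin8, Bmp3, Npnt, Mir703 and Arhgef6. H2-Eb1, carried by B and dendritic cells, had no UMI on day 7, which allows up to 5.37 CPM. It was at 62.9 CPM on day 12, at least 11.7-fold higher, and was at least 2-fold higher in the 3 other classes as well. Lower were the protease Mmp10 (42.8-fold), the chemokine Ccl3 (37.2-fold), Bmpr1b, Mt2, Ubb-ps, Ccdc162, Lrrc4, Atp5g2 and Atp5o.

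In fibroblast-like cells cartilage matrix transcripts included free RNA. Col2a1 stood there at 7750.3, 4718, 439.7 and 3265 CPM on days 7, 8, 10 and 12, beside 4740, 4015, 442 and 3842 CPM in monocyte- or macrophage-like cells, which should lack it. The cartilage matrix list had a median of -1.48 with 15 of 15 genes lower on day 12, which is not read as a difference in expression by fibroblasts. Hypoxia and glycolysis genes had a median of -1.01, with 10 of 16 lower and none higher. The lipid transporter Abca8a was 4.78-fold, the integrin Itga2 4.48-fold and Adam19 4.40-fold higher, with Mef2d, Btbd10, Dop1a, Baz2a and Tnks1bp1. Retnlg, a neutrophil gene, had no UMI on day 7, which allows up to 6.54 CPM, and was at 50.7 CPM on day 12, at least 7.74-fold higher. The bone morphogen Bmp2 was 6.74-fold and Polr2l 13.9-fold lower, with Mt2, Atp5o, Atp5g2, Mrpl23, Snhg6, Rbm3, Smim27 and Ndufs3. All 10 of these lower genes were at least 2-fold lower in the 3 other classes, as were 6 of 10 in reticular stromal cells.

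Across genes, which are not independent replicates, log2 ratios of neighbouring days correlated between pairs of the 4 classes. Pearson's r lay between 0.19 and 0.251 for day 8 over day 7, between 0.579 and 0.752 for day 10 over day 8 and between 0.358 and 0.495 for day 12 over day 10. For day 12 over day 7, the ratio behind the lists and named genes, it lay between 0.579 and 0.817, so part of these differences was shared by the 4 classes. Ribosomal protein genes took 18.2%, 20.1%, 14.5% and 10.9% of chondrocyte UMIs on days 7, 8, 10 and 12.

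Sex-linked genes had a median of -0.58 in chondrocytes. Cells with Y-linked UMIs and no Xist made up 28.3%, 12.9%, 0.00997% and 24.3% of cells on days 7, 8, 10 and 12, and cells with Xist and no Y-linked UMI 32.5%, 60.4%, 75.3% and 39.9%. Cells with both made up 9.52%, 8.61%, 0.319% and 15.7%. In chondrocytes the chondrocyte gate genes had a median of 0.51, the endothelial gate genes of 0.33, the erythroid gate genes of 2.07 and the fibroblast gate genes of 0.21.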
